A study of Mus musculus with 47 samples.

How the data were processed

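RNA from brown adipose tissue, white adipose tissue and gastrocnemius muscle of C57Bl6 mice was sequenced in 47 libraries. The immune status of the mice given human tumour cells is not stated. Per the labels, the deposited values are counts, whole numbers of reads per gene symbol, 1 column per library, for 24391 genes in each table. Per the labels' protocols, RNA was prepared from flash-frozen pieces with on-column DNase treatment. Brown fat libraries were made with QuantSeq, a kit that reads the 3-prime end of each transcript, with a module that adds unique molecular identifiers, and whether reads were collapsed by identifier before counting is not stated. White fat and muscle libraries were made with a directional kit that reads along the transcript. Per the submitters' processing notes, reads were trimmed with Trim Galore, aligned to mm9 with STAR 2.6.0a, counted with featureCounts 1.6.2 and analysed with edgeR 3.22.3. The gene annotation and the strand setting of the counting were not given, so no gene coordinates are printed, and symbols are as deposited.

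Samples were grouped by the tissue, tumour and treatment given in their labels, and the labels state no replication beyond separate samples. Each tissue was fitted apart with R 4.3.3 and edgeR 4.0.16, with its 3 groups in 1 quasi-likelihood model, TMM normalization factors and filterByExpr (minimum count 10, minimum total 15). The residual degrees of freedom were 14 in brown fat and 12 in white fat and in muscle. Tests were 2-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in that tissue and comparison. Fold changes are on the log2 scale with their standard error (SE). CPM is the count over each M counts of the library total after TMM scaling, where M stands for 1000 × 1000, given as mean ± SD over the libraries of a group. The 3 comparisons were IgG1 against NTB, 3P10 against IgG1 and 3P10 against NTB. Whether an effect differed between white fat and muscle was tested as the tissue-by-group interaction in a joint edgeR fit of both tissues. Brown fat was left out of that fit because its library kit and table differed.

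A gene called in IgG1 against NTB and in 3P10 against IgG1 with opposite signs was counted as an opposite call. Both comparisons share the IgG1 libraries, so noise in them alone makes the folds run against each other. The count was therefore set beside the number that independent lists of the same sizes would share, beside 20 simulations with a 3P10 group unchanged from IgG1 and 20 with no effect at all, and beside fits that gave each comparison its own IgG1 libraries.

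Lists of genes for pathways and for cell types were tested with camera in limma 3.58.1, which asks whether a list ranks above or below the other genes, with a preset correlation of 0.01 between genes. There were 35 lists, and p was adjusted over the lists tested in a comparison. Members called over all genes were counted, and so were members called when p was adjusted over the list alone. Beside each call, the adjusted p with a correlation estimated per list is given. In 28 list tests the median, the mean and the test differed in sign, and 0 of those were called.

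The lists, panels, tests, groups and rule for naming genes were fixed before the data were examined. Named genes were those of a panel per tissue, the 5 largest rises and 5 largest falls in IgG1 against NTB and in 3P10 against IgG1 among called genes whose groups did not overlap and whose mean was at least 1 CPM, up to 4 members with the smallest adjusted p of each list called, and Gdf15, Gfral and Ret. The text gives a part of the genes that met this rule. In counts of named genes, 1 gene is included that is not reported here. Genes outside the rule appear in checks of cell type, depot, reads or tissue differences, or are stated to be so.

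Library totals ran from 0.799 to 2.46 M counts in brown fat (median 1.16), from 18.6 to 80.7 M in white fat (median 26.0) and from 24.8 to 33.5 M in muscle (median 28.3). A gene with 0 counts in 1 library could lie at up to 3 counts, which is 1.22 to 3.76 CPM in brown fat, 0.0372 to 0.161 CPM in white fat and 0.0895 to 0.121 CPM in muscle. These floors cover counting error only. The ribosomal precursor Rn45s held 2.84 to 6.58% of brown fat counts. Tested on simulated data built from these libraries, the fit recovered 74.6 to 85.1% of 2-fold changes in brown fat, 55.2 to 61.2% in white fat and 52.2 to 56.7% in muscle. It recovered 26.9 and 23.9% of 2-fold differences between tissues. At 1.5-fold the share was 29.9 to 43.3% in brown fat, 14.9 to 17.9% in white fat and 7.46 to 13.4% in muscle.

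The alternatives were DESeq2 1.42.0 with its own size factors and Wald test, edgeR with RLE factors, no low-count filter, a filter of at least 1 CPM in 5 libraries, a fit of the compared groups alone, a model with a replicate block, and each library left out in turn. Lists were also tested with the estimated correlation, with fry and with the replicate block. A term for a library structure seen in muscle, and fits without the libraries that carry it, were added after seeing the data. Transcript lengths for 1 test were matched by symbol from a GRCm38 annotation, which covered 96.6% of the muscle genes tested. Principal components were computed on the edgeR log2 CPM of the 1000 most variable genes of a tissue. No sample was left out.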

Results

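Transcript levels were measured in 3 tissues of mice from 3 groups, 21 days after tumour inoculation. NTB mice bore no tumour, and the labels give them no antibody or dose, so IgG1 against NTB joins the tumour and the control antibody. IgG1 mice bore HT1080 tumours, a human fibrosarcoma cell line, and received a control antibody. 3P10 mice bore the same tumours and received 3P10, an antibody against GFRAL, the receptor for the circulating factor GDF15. GFRAL is made in the hindbrain and signals together with the kinase RET, and GDF15 lowers food intake through it. Both antibodies were given weekly at 3 mg/kg from the day of inoculation. Brown fat gave 6 NTB, 5 IgG1 and 6 3P10 libraries, and white fat and gastrocnemius muscle gave 5 libraries per group. Brown fat libraries were numbered group by group, so library order cannot be told apart from group in any brown fat comparison. Brown fat libraries held 0.799 to 2.46 M counts, white fat libraries 18.6 to 80.7 M and muscle libraries 24.8 to 33.5 M. After filtering, 8711 genes were tested in brown fat, 14402 in white fat and 13283 in muscle.

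The receptor itself was all but undetected in these tissues. Gfral had 0 reads in brown fat and muscle, which allows up to 1.22 to 3.76 CPM per brown fat library and 0.0895 to 0.121 CPM per muscle library, and 1 read in white fat, in a 3P10 library. Its ligand Gdf15 had 25 reads over the 17 brown fat libraries, 168 over the 15 white fat libraries and 46 over the 15 muscle libraries. White fat Gdf15 gave a log2 fold change of -0.57, SE 0.54, adjusted p = 0.514 in IgG1 against NTB. Ret, the co-receptor, was read in every white fat and muscle library. In muscle Ret fell, with 5.06 to 12.2 CPM in NTB and 0.863 to 3.41 CPM in IgG1, adjusted p = 0.00451, and lay at 3.01 to 5.61 CPM in 3P10, adjusted p = 0.292 against IgG1 (n = 5 each). In white fat the Ret value in IgG1 against NTB was -1.51, SE 0.61, adjusted p = 0.117.

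**Figure D1:**
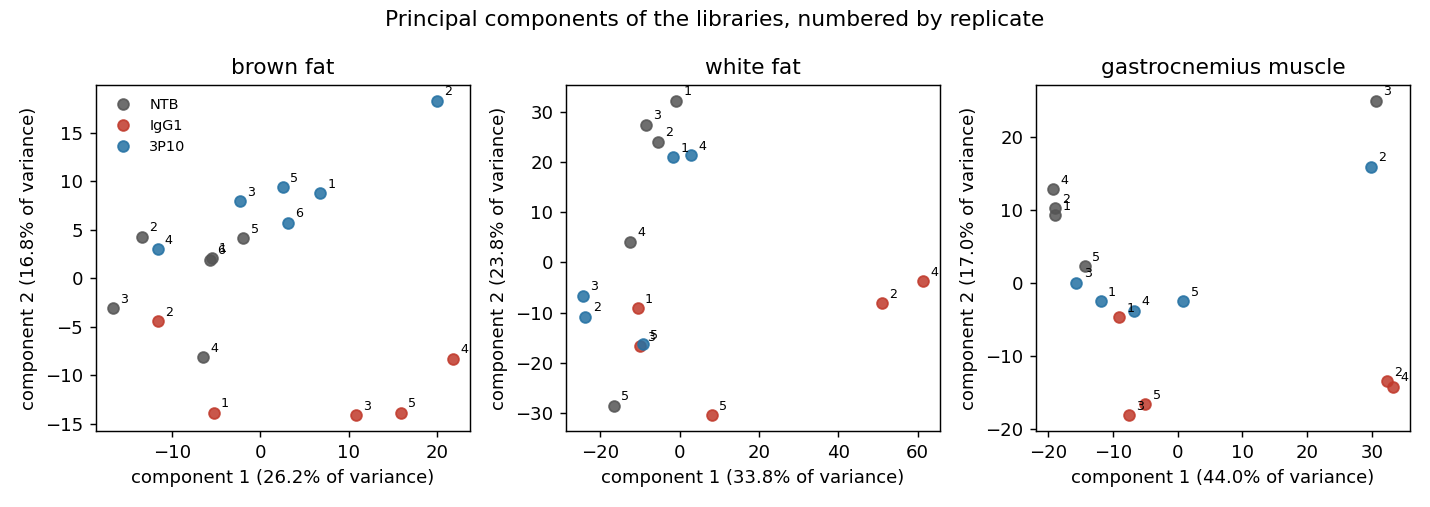
Libraries of each tissue on the first 2 principal components of the 1000 most variable genes, 1 point per library, coloured by group, with the percent of variance on each axis. The 4 muscle libraries far to 1 side come from all 3 groups, and white fat IgG1 replicates 2 and 4 lie apart from the other 13 libraries.

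The first component held 26.2% of the variance in brown fat, 33.8% in white fat and 44.0% in muscle. In muscle it parted NTB replicate 3, IgG1 replicates 2 and 4 and 3P10 replicate 2, at 29.9 to 33.3, from the other 11 libraries, which reached 0.907 at most. In white fat IgG1 replicates 2 and 4 lay at 51.0 and 61.4, IgG1 replicate 5 at 8.20 and the others at 2.85 or lower. Both of those white fat libraries also held the most Ucp1, the uncoupling protein of thermogenic fat, at 3286 and 3143 CPM against 37.1 to 712 CPM in the other 13. White fat IgG1 replicate 4 held 283 CPM of the keratin Krt14, against up to 0.818 CPM in NTB and 0.660 CPM in 3P10.

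Brown fat burns fuel for heat under sympathetic drive, and the first question was what differed in it between IgG1 and NTB. The beta-3 adrenergic receptor gene Adrb3, which carries that drive, fell by 1.85, SE 0.22, adjusted p = 2.01e-04, from 339 ± 116 CPM in NTB (n = 6) to 94.2 ± 32.9 CPM in IgG1 (n = 5). Adrb1 fell by 0.66 and Ucp1 by 0.41, SE 0.11, adjusted p = 0.0359, while Dio2, which makes active thyroid hormone inside the cell, rose by 1.72 (SE 0.39). The cytochrome P450 genes Cyp2b10 and Cyp2e1 rose by 5.09 (SE 0.67) and 2.21 (SE 0.33). The cell cycle inhibitor Cdkn1a rose by 2.21, SE 0.37, adjusted p = 0.00387. The lysosomal genes Gpnmb and Ctss rose by 4.26 (SE 0.69) and 1.08 (SE 0.23), with 6 reads of Gpnmb over all NTB libraries and 106 over all IgG1 libraries. Cyp26b1, which breaks down retinoic acid, fell by 1.93, and Eif4ebp1, a brake on translation, by 0.78. The neuronal splicing factor gene Nova1 rose by 1.04.

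Of 19 measured glucocorticoid response genes in brown fat, 2 rose, 0 fell and 17 did not pass, and 8 rose when adjusted over the list alone. Their median was 0.55, and the list ranked higher in IgG1 (adjusted p = 1.67e-05 by camera, adjusted p = 0.412 with an estimated correlation). Glutamine synthetase, Glul, rose by 0.72, and Fkbp5 gave 1.45, SE 0.48, adjusted p = 0.104. Among 22 fatty acid beta-oxidation genes 3 rose, 4 when adjusted over the list alone, including Acadm at 0.45 and Echs1 at 0.35 (adjusted p = 0.00630 by camera, adjusted p = 0.412 with an estimated correlation). Of 18 adipocyte identity genes 2 rose, 6 when adjusted over the list alone, with Adipoq at 0.47 (adjusted p = 0.00934 by camera, adjusted p = 0.457 with an estimated correlation). The lipase gene Pnpla2 rose by 0.38. Of 31 proteasome subunit genes 1 rose, 5 when adjusted over the list alone, and that 1 was Psma6 at 0.67 (adjusted p = 0.00381 by camera, adjusted p = 0.472 with an estimated correlation). Among 21 atrophy genes 3 rose and 1 fell, counts that stood when adjusted over the list alone, with Fbxo31 at 1.12 (adjusted p = 0.0129 by camera, adjusted p = 0.457 with an estimated correlation). Of 12 acute phase and cytokine response genes 0 passed, and 4 rose when adjusted over the list alone (adjusted p = 0.0129 by camera, adjusted p = 0.412 with an estimated correlation).

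Thermogenic brown-fat genes went both ways in IgG1 against NTB, with 2 of 18 higher and 3 lower (adjusted p = 0.0529 by camera, adjusted p = 0.457 with an estimated correlation). Lists that ranked lower held 0 called members, also when adjusted over the list alone. These were 16 interferon response genes (adjusted p = 0.00381 by camera, adjusted p = 0.472 with an estimated correlation) and 19 collagen and extracellular matrix genes (adjusted p = 0.00683 by camera, adjusted p = 0.472 with an estimated correlation). Also lower were 12 fast-fibre contractile genes (adjusted p = 0.0129 by camera, adjusted p = 0.577 with an estimated correlation) and 15 skeletal muscle markers, whose median was -0.73 (adjusted p = 0.00630 by camera, adjusted p = 0.568 with an estimated correlation). The muscle genes varied within each group, with an estimated muscle share of 0 to 1.17% of a library.

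In all, 259 of 8711 genes passed in brown fat of IgG1 against NTB, 162 higher and 97 lower, and 47 of them changed at least 2-fold. With the muscle marker score as a term, a fit chosen after the result was seen, 86 passed, 82 of them among the 259. For the 177 calls that ended, the median fold went from 0.57 to 0.55 in the same direction and the median SE from 0.14 to 0.15. In a fit of the IgG1 and NTB libraries alone 154 passed. The count moved with single libraries. It was 554 without IgG1 replicate 2 but 34 without IgG1 replicate 5, 76 without IgG1 replicate 3, 107 without IgG1 replicate 4 and 154 without IgG1 replicate 1. Without NTB replicates 1, 3, 5 or 6 it was 152, 159, 149 or 129. Of 23 genes named here or in the closing observations and called, 20 changed the same way in every IgG1 library, and in Cdkn1a, Glul and Pnpla2 4 of 5 did. The calls of 10 of the 23 held without any single library, those of Adrb3, Cyp2b10, Cyp2e1, Cdkn1a, Gpnmb, Ctss, Adipoq, Psma6, Fbxo31 and Serpinh1. Without IgG1 replicate 5, 13 of the 23 calls ended, among them Dio2, Ucp1 and Adrb1.

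**Figure D2:**
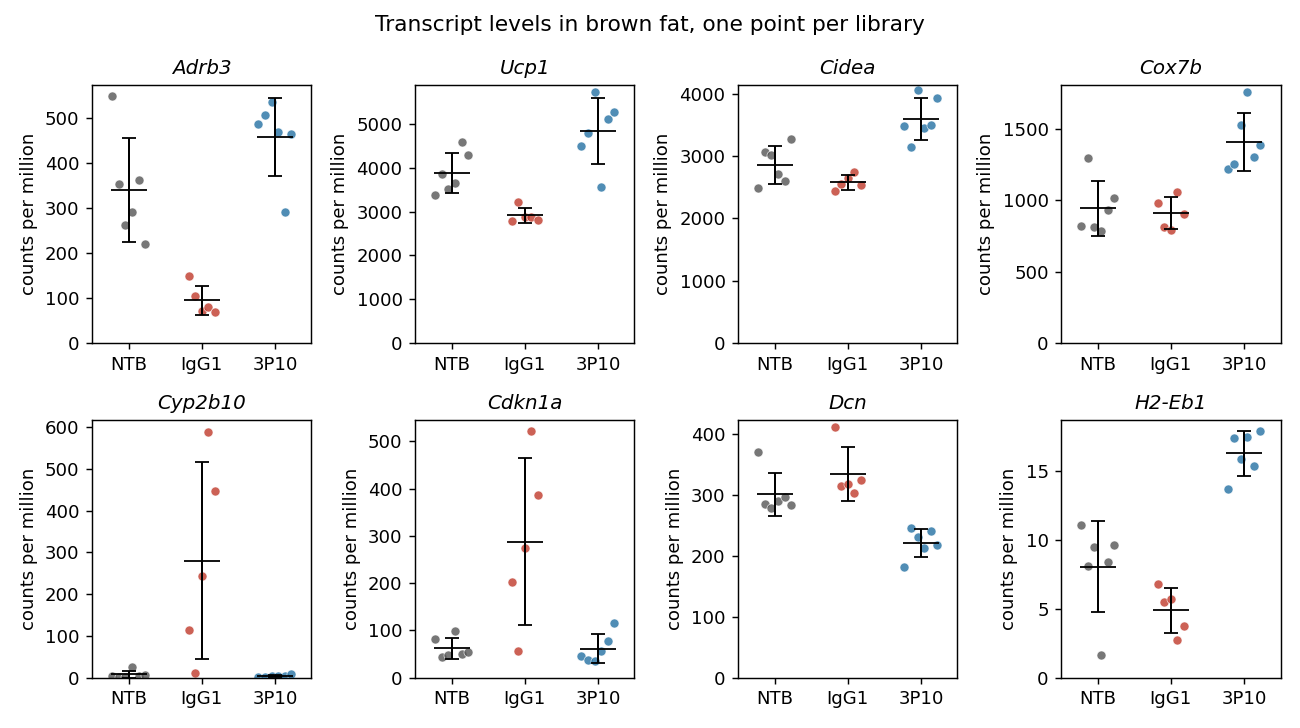
Transcript levels of 8 genes in brown fat in CPM on the vertical axis by group on the horizontal axis, 1 point per library, with the mean as a bar and the SD as error bars. Adrb3 lay at 219 to 548 CPM in NTB, 69.5 to 148 CPM in IgG1 and 289.7 to 535 CPM in 3P10.

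The question behind 3P10 against IgG1 was what blocking GFRAL changed in tumour-bearing mice. In brown fat Adrb3 rose by 2.30, SE 0.22, adjusted p = 4.11e-06, to 458 ± 86.5 CPM (n = 6). Adrb1 rose by 1.02 (SE 0.17), Ucp1 by 0.73 (SE 0.11) and the lipid droplet gene Cidea by 0.48 (SE 0.09). Dio2 fell by 1.87, Cyp2b10 fell by 6.36, SE 0.75, adjusted p = 5.53e-05, Cyp2e1 by 2.73 and Cdkn1a by 2.28. Gpnmb fell by 1.39, Nova1 by 1.90, Psma6 by 0.61, Echs1 by 0.38 and Pnpla2 by 0.37. Cyp26b1 rose by 2.07 and Eif4ebp1 by 1.55, SE 0.19, adjusted p = 5.53e-05. H2-Eb1, which encodes a chain of the class II molecules that present antigen, rose by 1.75, SE 0.30, adjusted p = 8.90e-04.

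Thermogenic brown-fat genes ranked higher in 3P10, with 10 of 18 higher and 2 lower, and 11 and 3 when adjusted over the list alone (adjusted p = 1.74e-05 by camera, adjusted p = 0.0726 with an estimated correlation). Otop1 rose by 0.70, Letmd1 by 0.57 and the brown-fat regulator Prdm16 by 0.73. Of 53 oxidative phosphorylation genes 16 rose and 4 fell, 23 and 6 when adjusted over the list alone. Cox7b rose by 0.63, Cox6b1 by 0.57 and Uqcrfs1 by 0.86 (adjusted p = 0.00110 by camera, adjusted p = 0.806 with an estimated correlation). Of 16 lipolysis genes 3 rose and 1 fell, 5 and 1 when adjusted over the list alone, with the lipase gene Lipe at 0.35 (adjusted p = 0.00191 by camera, adjusted p = 0.274 with an estimated correlation). Among 17 fatty acid synthesis genes 3 rose and 1 fell, 7 and 2 when adjusted over the list alone. Acaca rose by 0.70, Elovl5 by 0.58 and Slc25a1 by 0.45 (adjusted p = 0.0189 by camera, adjusted p = 0.789 with an estimated correlation).

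Glucocorticoid response genes ranked lower in 3P10 brown fat, with 8 of 19 lower and 2 higher, 9 and 2 when adjusted over the list alone (adjusted p = 7.55e-05 by camera, adjusted p = 0.532 with an estimated correlation). Fkbp5 fell by 2.89, SE 0.54, adjusted p = 0.00172, the transcription factor gene Zbtb16 fell by 2.61, Klf9 by 0.59 and Glul by 0.65. Of 10 fibroblast and preadipocyte markers 3 fell, also when adjusted over the list alone. Dcn fell by 0.59, Cd34 by 0.66 and Pdgfrb by 0.48 (adjusted p = 0.0138 by camera, adjusted p = 0.586 with an estimated correlation). Of 10 endothelial markers Pecam1 fell, by 0.52, and 2 fell when adjusted over the list alone (adjusted p = 0.00768 by camera, adjusted p = 0.789 with an estimated correlation).

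In this comparison 1013 genes passed, 527 higher and 486 lower in 3P10, and 128 changed at least 2-fold. The count was 646 without IgG1 replicate 3 and 650 without IgG1 replicate 5. All 38 named and called genes had each of the 6 3P10 libraries on the called side of the IgG1 mean, and the groups did not overlap in 20. Without any single library, 32 of the 38 calls held. The calls of Cd34, Gpnmb, Pdgfrb, Prdm16, Lipe and Slc25a1 did not, and without IgG1 replicate 5 those of 5 of them ended.

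Brown fat also differed between 3P10 and NTB. There 501 genes passed, 264 higher and 237 lower, of which 25 changed at least 2-fold. Cox7b rose by 0.58 (SE 0.12), Cox6b1 by 0.51 (SE 0.11), Uqcrfs1 by 0.61, Letmd1 by 0.43, Cidea by 0.33, Otop1 by 0.36 and Acaca by 0.48. Lipe rose by 0.31, Eif4ebp1 by 0.77, H2-Eb1 by 1.03 and Gpnmb by 2.87. Dcn fell by 0.44, SE 0.10, adjusted p = 0.0140, Cd34 by 0.68, Pdgfrb by 0.59 and Zbtb16 by 1.81. Adrb3 gave 0.44, SE 0.19, adjusted p = 0.168 and Ucp1 0.32, SE 0.10, adjusted p = 0.0593. All 15 named and called genes changed the same way in each 3P10 library, and the calls of Cox6b1, Cox7b, Dcn, Eif4ebp1 and Letmd1 held without any single library. With the muscle marker score as a term, 313 passed, 273 of them among the 501. The count of 501 was 172 without NTB replicate 4, 188 without 3P10 replicate 6, 210 without 3P10 replicate 3 and 244 without NTB replicate 1. It was 286 without NTB replicate 3 and 290 without 3P10 replicate 4.

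Among lists in 3P10 against NTB, 9 of 53 oxidative phosphorylation genes rose and 1 fell in brown fat, 21 and 2 when adjusted over the list alone (adjusted p = 2.49e-06 by camera, adjusted p = 0.424 with an estimated correlation). Of 22 beta-oxidation genes 5 rose, and 9 rose and 1 fell when adjusted over the list alone (adjusted p = 2.00e-04 by camera, adjusted p = 0.110 with an estimated correlation). Of 18 thermogenic genes 3 rose, 6 when adjusted over the list alone (adjusted p = 4.77e-04 by camera, adjusted p = 0.110 with an estimated correlation). Of 16 lipolysis genes 3 rose, 5 when adjusted over the list alone (adjusted p = 4.77e-04 by camera, adjusted p = 0.110 with an estimated correlation). Of 18 adipocyte identity genes 4 rose, 7 when adjusted over the list alone (adjusted p = 4.77e-04 by camera, adjusted p = 0.280 with an estimated correlation). Of 17 fatty acid synthesis genes 3 rose, 5 when adjusted over the list alone (adjusted p = 0.00163 by camera, adjusted p = 0.424 with an estimated correlation). Cholesterol synthesis (adjusted p = 0.00424 by camera, adjusted p = 0.424 with an estimated correlation) and proteasome subunits (adjusted p = 0.00133 by camera, adjusted p = 0.424 with an estimated correlation) also ranked higher. Of 10 endothelial markers 5 fell, 8 when adjusted over the list alone (adjusted p = 1.04e-07 by camera, adjusted p = 0.126 with an estimated correlation). Of 10 fibroblast and preadipocyte markers 4 fell, 5 when adjusted over the list alone (adjusted p = 3.29e-05 by camera, adjusted p = 0.110 with an estimated correlation). Of 19 collagen and extracellular matrix genes 2 fell, 4 when adjusted over the list alone (adjusted p = 0.00133 by camera, adjusted p = 0.424 with an estimated correlation). Skeletal muscle markers (adjusted p = 3.29e-05 by camera, adjusted p = 0.424 with an estimated correlation) and fast-fibre contractile genes (adjusted p = 1.87e-04 by camera, adjusted p = 0.432 with an estimated correlation) ranked lower with 0 members called.

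White fat stores lipid, and the same question was put to it for IgG1 against NTB. The transcription factor gene Mycl rose by 3.50, SE 0.44, adjusted p = 0.00231, from 5.49 ± 2.46 CPM in NTB to 61.8 ± 23.6 CPM in IgG1 (n = 5 each). Irf4, which responds to fasting in fat, rose by 3.06 (SE 0.51), and the lipid transporter gene Mfsd2a by 7.54 (SE 1.52) from 14 reads over all NTB libraries, with 0.478 to 71.3 CPM in IgG1. Acot3 rose by 4.46. The nerve growth factor receptor gene Ngfr fell by 2.97, SE 0.35, adjusted p = 0.00162, from 7.12 ± 0.916 to 0.885 ± 0.332 CPM. Akr1cl fell by 3.97, the phospholipase gene Pla2g2e by 3.44 and the chemokine gene Ccl8 fell by 3.20. Leptin, Lep, gave -1.28, SE 0.63, adjusted p = 0.189, and Ucp1 gave 2.13, SE 0.98, adjusted p = 0.165.

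Of 20 glucocorticoid response genes 9 rose in IgG1 white fat, 11 when adjusted over the list alone, and 0 fell (adjusted p = 1.59e-06 by camera, adjusted p = 0.212 with an estimated correlation). Fkbp5 rose by 2.06, SE 0.39, adjusted p = 0.00909, the metallothionein genes Mt1 and Mt2 by 1.58 and 1.87, and Klf15 by 0.58. Of 18 circadian clock genes 8 rose and 1 fell, 10 and 3 when adjusted over the list alone (adjusted p = 1.09e-05 by camera, adjusted p = 0.212 with an estimated correlation). Per1 rose by 1.33, SE 0.24, adjusted p = 0.00880, Usp2 by 1.61, Hlf by 1.71 and Cry1 by 0.95. Of 22 beta-oxidation genes 4 rose, 17 when adjusted over the list alone (adjusted p = 4.60e-08 by camera, adjusted p = 0.431 with an estimated correlation). Acot2, which splits acyl-CoA in mitochondria, rose by 1.03, SE 0.14, adjusted p = 0.00350, Eci2 by 0.65, Eci1 by 1.11 and Acads by 0.68. Pnpla2 rose by 0.58.

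Of 24 atrophy genes 5 rose and 1 fell, 6 and 1 when adjusted over the list alone (adjusted p = 0.00723 by camera, adjusted p = 0.325 with an estimated correlation), and Fbxo31 rose by 1.41. Of 54 oxidative phosphorylation genes 1 rose, 0 when adjusted over the list alone, with a median of 0.71 (adjusted p = 3.29e-09 by camera, adjusted p = 0.632 with an estimated correlation). Of 18 thermogenic genes Slc27a2 rose, by 3.26, and 0 passed when adjusted over the list alone (adjusted p = 0.00723 by camera, adjusted p = 0.670 with an estimated correlation). Without NTB replicate 3, IgG1 replicates 2 and 4 and 3P10 replicate 2, these genes ranked lower in place of higher (adjusted p = 0.286). Of 20 glycolysis and glycogen genes 1 rose, also when adjusted over the list alone (adjusted p = 0.00599 by camera, adjusted p = 0.587 with an estimated correlation). Of 31 proteasome genes 0 passed (adjusted p = 0.0203 by camera, adjusted p = 0.723 with an estimated correlation), and of 12 slow-fibre contractile genes 0 passed, 7 when adjusted over the list alone (adjusted p = 0.0473 by camera, adjusted p = 0.670 with an estimated correlation).

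Of 22 collagen and extracellular matrix genes 13 fell in IgG1 white fat, 18 when adjusted over the list alone, with a median of -1.37 (adjusted p = 1.66e-17 by camera, adjusted p = 0.212 with an estimated correlation). Col1a1 fell by 2.35, SE 0.49, adjusted p = 0.0139, from 396 ± 53.4 to 77.8 ± 66.0 CPM. Col1a2 fell by 2.15, Col6a3 fell by 1.91, Fbn1 by 1.68, SE 0.25, adjusted p = 0.00394, Fn1 by 1.58 and Lum fell by 1.84. Of 12 fibroblast and preadipocyte markers 3 fell, 6 when adjusted over the list alone, with Cd34 lower by 1.06 and Mfap5 lower by 1.29 (adjusted p = 1.36e-05 by camera, adjusted p = 0.298 with an estimated correlation). Of 25 cell cycle genes 11 fell, 16 when adjusted over the list alone (adjusted p = 2.62e-09 by camera, adjusted p = 0.215 with an estimated correlation). Top2a fell by 2.17, Ccnb2 by 2.21, Ccnb1 by 1.78 and Cenpe by 1.38. Of 25 interferon response genes 2 fell, Gbp2 by 0.89 and Isg15 by 0.90, and 7 fell when adjusted over the list alone (adjusted p = 4.72e-04 by camera, adjusted p = 0.501 with an estimated correlation). Of 17 macrophage markers Ccr2, the receptor that draws monocytes into tissue, fell by 1.02, and 2 fell when adjusted over the list alone (adjusted p = 0.00599 by camera, adjusted p = 0.632 with an estimated correlation).

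In white fat 1245 of 14402 genes passed in IgG1 against NTB, 589 higher and 656 lower, and 484 changed at least 2-fold. The count was 2212 without IgG1 replicate 1 and 2354 without IgG1 replicate 3. It was 439, 463 and 510 without IgG1 replicates 2, 4 and 5, and 344, 436 and 540 without NTB replicates 1, 2 and 3. Of 44 named and called genes 41 changed the same way in every IgG1 library, while Eci1 and Acads did in 4 of 5 and Slc27a2 in 3 of 5. The calls of 26 held without any single library, and the most that ended were 16, without NTB replicate 1. The calls of Acot2, Col6a3, Fbn1, Fbxo31, Mycl, Ngfr and Usp2 also held under each other alternative run. In fits without NTB replicate 3, IgG1 replicates 2 and 4 and 3P10 replicate 2, which left 3 IgG1 libraries, 84 genes passed, 73 of them among the 1245.

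**Figure D3:**
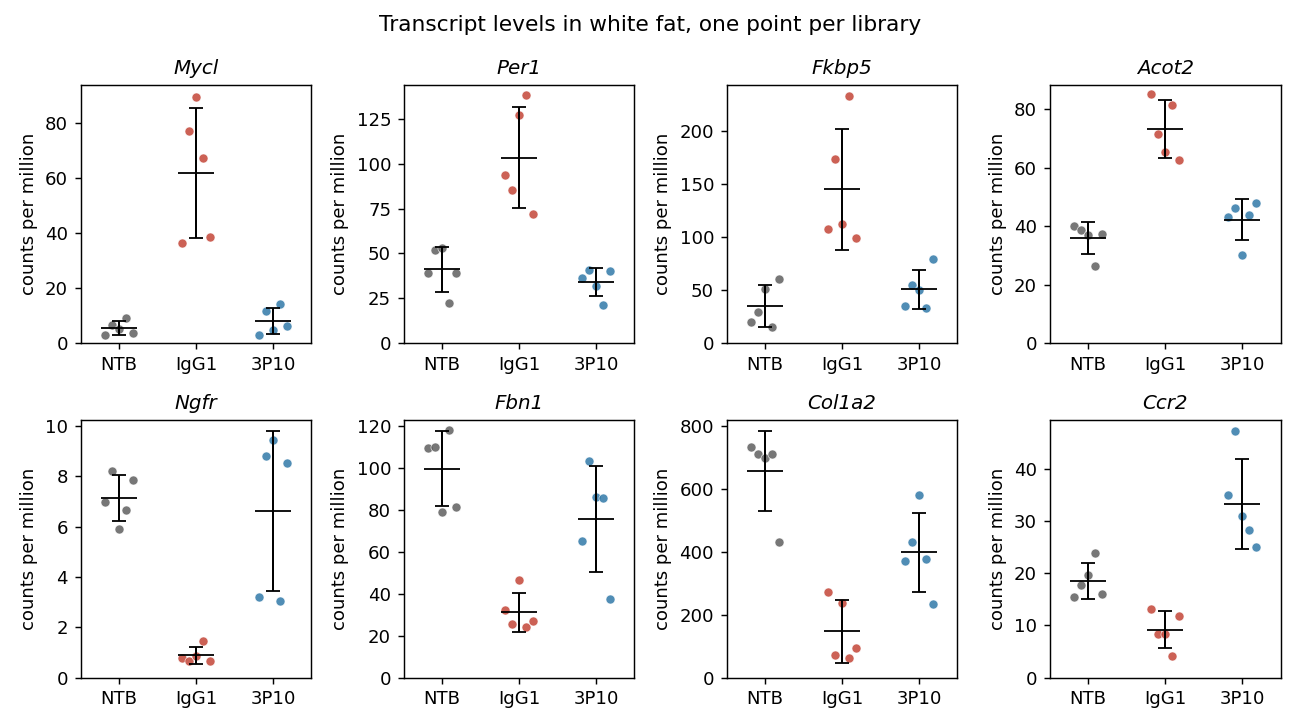
Transcript levels of 8 genes in white fat in CPM on the vertical axis by group on the horizontal axis, 1 point per library, with the mean as a bar and the SD as error bars. Mycl lay at 36.4 to 89.6 CPM in IgG1 against 3.02 to 9.18 CPM in NTB and 2.91 to 14.1 CPM in 3P10.

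With 3P10 against IgG1 in white fat, several genes that had passed in IgG1 against NTB passed with the opposite sign. Mycl fell by 2.99, SE 0.43, adjusted p = 0.00602, Irf4 fell by 2.95, Mfsd2a fell by 6.50 and Acot3 by 3.19, and Ngfr rose by 2.86, SE 0.35, adjusted p = 0.00602. Akr1cl rose by 5.72, Ccl8 by 3.41 and Pla2g2e by 1.89. Of 17 macrophage markers 6 rose, 11 when adjusted over the list alone (adjusted p = 4.21e-09 by camera, adjusted p = 0.330 with an estimated correlation). Ccr2 rose by 1.87, SE 0.26, adjusted p = 0.00602, to 33.3 ± 8.61 CPM. Its ligand gene Ccl2 also rose, to 2.07 ± 1.24 CPM. C1qc rose by 1.35, Mpeg1 by 0.99, Lyz2 by 0.94 and Adgre1, which encodes the surface marker of mature macrophages, by 0.93. Of 25 interferon response genes 7 rose, 13 when adjusted over the list alone, with Mx1 at 1.28, Ifit3 at 0.95, Ifi44 at 0.92 and Isg15 at 0.92 (adjusted p = 1.17e-07 by camera, adjusted p = 0.330 with an estimated correlation).

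Of 22 collagen and extracellular matrix genes 8 rose in 3P10 against IgG1 white fat, 17 when adjusted over the list alone (adjusted p = 6.73e-12 by camera, adjusted p = 0.330 with an estimated correlation). Col1a1 rose by 1.80, Col1a2 by 1.43, Col6a3 by 1.46, Fbn1 by 1.28, SE 0.24, adjusted p = 0.0144, Fn1 by 1.02 and Lum by 1.55. Of 12 fibroblast and preadipocyte markers 3 rose, 6 when adjusted over the list alone, among them Cd34 at 0.90 and Mfap5 at 0.86 (adjusted p = 9.86e-05 by camera, adjusted p = 0.357 with an estimated correlation). Of 20 glucocorticoid response genes 6 fell, 8 when adjusted over the list alone (adjusted p = 2.13e-05 by camera, adjusted p = 0.330 with an estimated correlation). Fkbp5 fell by 1.53, Mt1 by 1.35, Glul by 1.13 and Klf15 by 0.62. Of 18 circadian clock genes 7 fell and 1 rose, 8 and 3 when adjusted over the list alone (adjusted p = 5.74e-05 by camera, adjusted p = 0.330 with an estimated correlation). Per1 fell, with 72.2 to 138 CPM in IgG1 and 21.4 to 41.0 CPM in 3P10, adjusted p = 0.00602, Usp2 fell by 1.31, Hlf by 1.44 and Cry1 by 1.09.

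Of 22 beta-oxidation genes 5 fell in 3P10 against IgG1 white fat, 18 when adjusted over the list alone (adjusted p = 4.21e-09 by camera, adjusted p = 0.357 with an estimated correlation), with Acot2 lower by 0.80, Eci1 by 1.16, Eci2 by 0.70 and Acads by 0.74. Pnpla2 fell by 0.65 and Fbxo31 by 1.05. Of 54 oxidative phosphorylation genes 2 fell, 27 when adjusted over the list alone (adjusted p = 6.73e-12 by camera, adjusted p = 0.489 with an estimated correlation). Of 20 glycolysis and glycogen genes 2 fell, also when adjusted over the list alone (adjusted p = 0.0366 by camera, adjusted p = 0.538 with an estimated correlation). Of 18 thermogenic genes 0 passed (adjusted p = 0.00267 by camera, adjusted p = 0.538 with an estimated correlation), and Ucp1 gave -2.12, SE 0.98, adjusted p = 0.172. Without NTB replicate 3, IgG1 replicates 2 and 4 and 3P10 replicate 2, the thermogenic genes ranked in the other direction (adjusted p = 0.424). With 0 members called, 25 cell cycle genes (adjusted p = 0.00384 by camera, adjusted p = 0.489 with an estimated correlation), 11 T and NK cell markers (adjusted p = 0.0155 by camera, adjusted p = 0.489 with an estimated correlation), 12 fast-fibre contractile genes (adjusted p = 0.00101 by camera, adjusted p = 0.501 with an estimated correlation) and 15 skeletal muscle markers (adjusted p = 0.00118 by camera, adjusted p = 0.538 with an estimated correlation) ranked higher. The T cell genes Cd3e and Cd8a themselves had 11 and 2 reads over the 15 white fat libraries, too few to be tested.

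In white fat 1068 genes passed in 3P10 against IgG1, 570 higher and 498 lower, and 394 changed at least 2-fold. The count was 1818 and 2304 without IgG1 replicates 1 and 3, and 127, 175 and 389 without IgG1 replicates 2, 4 and 5. Without 3P10 replicates 1, 2, 3 and 4 it was 321, 574, 158 and 554. Each of 43 named and called genes changed the same way in all 5 3P10 libraries. The calls of Acot2, Akr1cl, Ccr2, Fbn1, Irf4, Mycl, Ngfr and Per1 held without any single library. Without IgG1 replicate 2, 33 of the 43 calls ended, and without IgG1 replicate 4, 31 ended. In fits without NTB replicate 3, IgG1 replicates 2 and 4 and 3P10 replicate 2, edgeR called 0 genes, with 2321 at an unadjusted p under 0.05. In a fit of the 3P10 and IgG1 libraries alone edgeR called 105, and DESeq2 on all libraries called 2282.

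Between 3P10 and NTB white fat, edgeR called 0 of 14402 genes, with 542 at an unadjusted p under 0.05, and DESeq2 called 19. Ngfr gave -0.11, SE 0.32, adjusted p = 1, Mycl 0.51, SE 0.42, adjusted p = 1, Ccnb2 -1.85, SE 0.51, adjusted p = 0.838 and Ccr2 0.84, SE 0.25, adjusted p = 0.894. Whole lists still ranked apart. Acute phase and cytokine response genes (23 measured, median 0.33) ranked higher in 3P10 (adjusted p = 5.64e-06 by camera, adjusted p = 0.00518 with an estimated correlation), as did 6 neutrophil markers, of which 3 were higher when adjusted over the list alone (adjusted p = 2.41e-06 by camera, adjusted p = 0.0128 with an estimated correlation). Of 17 macrophage markers 2 were higher when adjusted over the list alone (adjusted p = 7.63e-09 by camera, adjusted p = 0.210 with an estimated correlation). Of 25 cell cycle genes 2 were lower when adjusted over the list alone (adjusted p = 1.16e-10 by camera, adjusted p = 0.178 with an estimated correlation), and 22 collagen and extracellular matrix genes ranked lower (adjusted p = 4.39e-04 by camera, adjusted p = 0.781 with an estimated correlation). Skeletal muscle markers (adjusted p = 7.71e-12 by camera, adjusted p = 0.210 with an estimated correlation), fast-fibre genes (adjusted p = 1.69e-10 by camera, adjusted p = 0.210 with an estimated correlation) and denervation and myogenic genes (adjusted p = 0.00447 by camera, adjusted p = 0.210 with an estimated correlation) ranked higher, each with 2 members higher when adjusted over the list alone. Slow-fibre genes (adjusted p = 0.00216 by camera, adjusted p = 0.644 with an estimated correlation), interferon response genes (adjusted p = 0.00348 by camera, adjusted p = 0.753 with an estimated correlation) and atrophy genes (adjusted p = 0.00447 by camera, adjusted p = 0.249 with an estimated correlation) ranked higher as well.

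In gastrocnemius muscle the question was which wasting genes passed in IgG1 against NTB. Ddit4, which restrains mTOR signalling, rose by 3.70, SE 0.63, adjusted p = 0.00408, with 5.35 to 12.3 CPM in NTB and 17.8 to 239.8 CPM in IgG1 (n = 5 each). Fbxo32, the muscle ubiquitin ligase atrogin-1, rose by 1.45, SE 0.30, adjusted p = 0.0125. The companion ligase gene Trim63 gave 0.81, SE 0.32, adjusted p = 0.154, myostatin, Mstn, gave 0.37, SE 0.15, adjusted p = 0.171 and the fast myosin gene Myh4 gave 0.09, SE 0.21, adjusted p = 0.853. Of 24 atrophy genes 9 rose, 13 when adjusted over the list alone, and 0 fell (adjusted p = 1.52e-10 by camera, adjusted p = 0.0172 with an estimated correlation). Eif4ebp1 rose by 1.80 (SE 0.31), Gadd45a by 1.08 (SE 0.24) and Sesn1 by 0.87. Of 22 autophagy and lysosome genes 4 rose, 10 when adjusted over the list alone (adjusted p = 4.51e-05 by camera, adjusted p = 0.0964 with an estimated correlation), with Bnip3 at 1.16, Map1lc3b at 0.83, Ctsl at 0.89 and Lamp2 at 0.54. Of 31 proteasome genes 1 rose, also when adjusted over the list alone (adjusted p = 0.00475 by camera, adjusted p = 0.635 with an estimated correlation).

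Of 20 glucocorticoid response genes 10 rose in IgG1 muscle, 12 when adjusted over the list alone (adjusted p = 1.42e-14 by camera, adjusted p = 0.0101 with an estimated correlation). Cebpd rose by 3.12, SE 0.51, adjusted p = 0.00294, the kinase gene Sgk1 by 1.37, SE 0.19, adjusted p = 0.00125, Fkbp5 by 1.54 (SE 0.32), Klf15 by 0.90 and Mt2 by 4.04. Of 17 acute phase and cytokine response genes 7 rose, 10 when adjusted over the list alone (adjusted p = 3.24e-08 by camera, adjusted p = 0.0109 with an estimated correlation), with Il6ra at 2.45, Socs3 at 1.42 and Cebpb at 1.03. Of 18 circadian clock genes 3 rose, 4 when adjusted over the list alone (adjusted p = 0.00694 by camera, adjusted p = 0.105 with an estimated correlation). Per1 rose by 1.15 and Cry2 by 0.78. Of 21 integrated stress response genes Chac1, which degrades glutathione, rose by 2.45 (SE 0.37), and 2 rose when adjusted over the list alone (adjusted p = 0.0107 by camera, adjusted p = 0.503 with an estimated correlation). Of 18 adipocyte identity genes 1 rose, also when adjusted over the list alone (adjusted p = 8.84e-04 by camera, adjusted p = 0.505 with an estimated correlation). Outside the lists, the chemokine gene Cxcl13 rose by 3.93, Doc2b by 2.52, SE 0.30, adjusted p = 4.58e-04, Gabrr2 by 1.96 and Abca4 by 1.74. Dio2 fell by 1.90 and the nicotinamide riboside kinase gene Nmrk2 by 2.35.

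Of 22 collagen and extracellular matrix genes 12 fell and 1 rose in IgG1 muscle, 18 and 1 when adjusted over the list alone, with a median of -1.03 (adjusted p = 6.35e-20 by camera, adjusted p = 0.0250 with an estimated correlation). Col6a2 fell by 1.68, SE 0.21, adjusted p = 8.69e-04, from 78.9 ± 15.1 to 24.7 ± 8.10 CPM, Col6a1 by 1.29, Postn by 1.26, Sparc by 1.04 and Fbn1 by 1.62. Kera fell by 3.10, Mfap4 by 2.94, the tendon gene Tnmd fell by 2.55, Scg3 by 2.63 and Rsph1 by 3.01. Of 12 fibroblast and preadipocyte markers 4 fell, also when adjusted over the list alone (adjusted p = 6.91e-04 by camera, adjusted p = 0.261 with an estimated correlation), with Cd34 lower by 0.65. Of 12 endothelial markers 1 fell, 2 when adjusted over the list alone (adjusted p = 1.68e-04 by camera, adjusted p = 0.503 with an estimated correlation). Of 19 cell cycle genes 5 fell, also when adjusted over the list alone (adjusted p = 0.0107 by camera, adjusted p = 0.137 with an estimated correlation), with Mki67 lower by 2.41, Top2a by 1.61 and Aurka by 0.87. Of 54 oxidative phosphorylation genes 1 fell, 0 when adjusted over the list alone (adjusted p = 4.51e-05 by camera, adjusted p = 0.631 with an estimated correlation), and 23 beta-oxidation genes ranked lower with 0 called (adjusted p = 0.0353 by camera, adjusted p = 0.631 with an estimated correlation).

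In muscle 744 of 13283 genes passed in IgG1 against NTB, 356 higher and 388 lower, and 267 changed at least 2-fold. The count was 1307 without IgG1 replicate 1, 447 without IgG1 replicate 2 and 331 without IgG1 replicate 4. It was 327, 347 and 401 without NTB replicates 1, 2 and 4. Of 49 named and called genes 46 changed the same way in every IgG1 library, and Mt1, Mt2 and Ctsl did in 4 of 5. The calls of 36 held without any single library, and the most that ended were 13, without NTB replicate 1, among them Bnip3, Lamp2, Map1lc3b and Klf15. With a term for the 4 libraries that stood apart the count was 2455, which held all 744, and without those 4 it was 876, of which 512 were among the 744. In a fit of the IgG1 and NTB libraries alone it was 347.

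**Figure D4:**
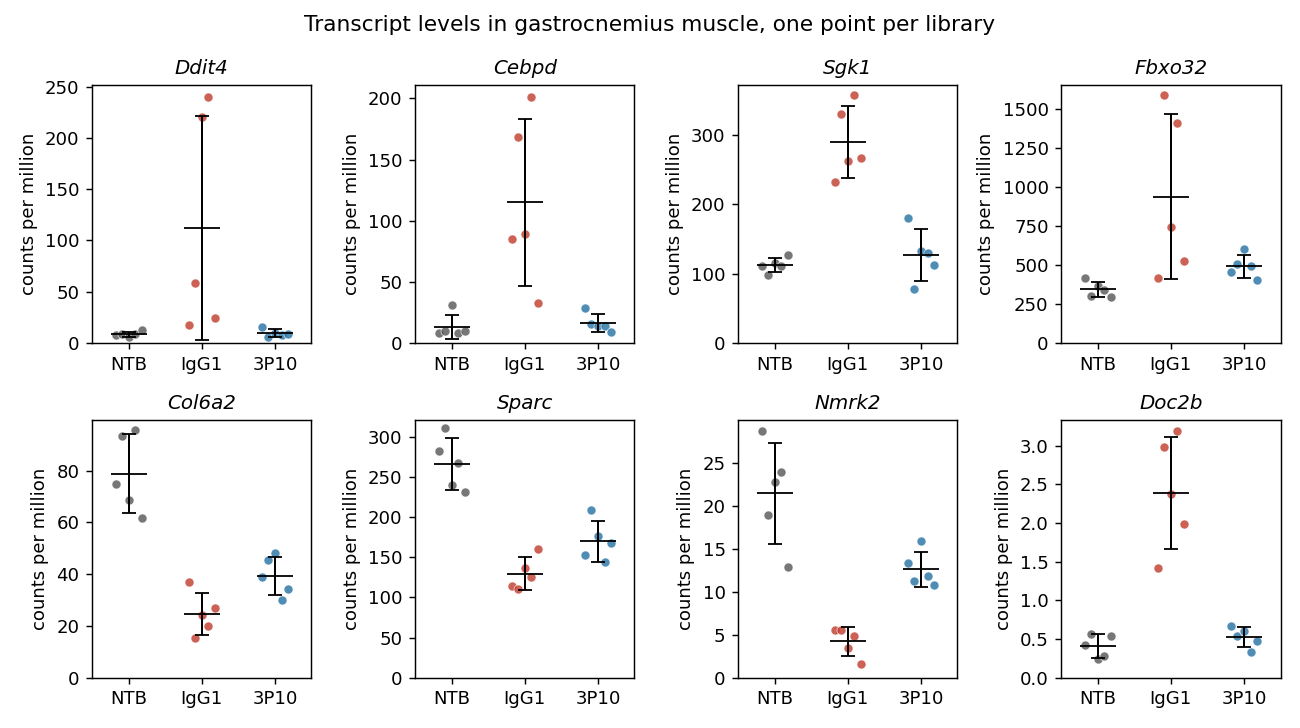
Transcript levels of 8 genes in gastrocnemius muscle in CPM on the vertical axis by group on the horizontal axis, 1 point per library, with the mean as a bar and the SD as error bars. Sgk1 lay at 232 to 358 CPM in IgG1 against 97.6 to 126 CPM in NTB and 78.2 to 180.2 CPM in 3P10.

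Under 3P10 a small set of muscle genes passed, 28 in all, 12 higher and 16 lower, of which 20 changed at least 2-fold, while 1430 lay at an unadjusted p under 0.05. Ddit4 fell by 3.58, SE 0.63, adjusted p = 0.0294, Cebpd by 2.82, Sgk1 by 1.19, SE 0.19, adjusted p = 0.0142, Per1 by 1.28, Doc2b fell by 2.19, SE 0.29, adjusted p = 0.00464, Abca4 by 1.46 and Gabrr2 by 1.85. Nmrk2 rose by 1.58 (SE 0.28), Dio2 by 1.58, Rsph1 by 1.85 and Ccr2 by 1.54. H2-Eb1 rose by 1.20, SE 0.23, adjusted p = 0.0445. Fbxo32 gave -0.93, SE 0.30, adjusted p = 0.237, Eif4ebp1 -1.33, SE 0.30, adjusted p = 0.0808, Fkbp5 -1.06, SE 0.31, adjusted p = 0.183 and Col6a2 0.67, SE 0.21, adjusted p = 0.222. Each of 12 named and called genes changed the same way in all 5 3P10 libraries. Only the calls of Abca4 and Doc2b held without any single library. The count of 28 was 231 without IgG1 replicate 1, and 11, 10, 8 and 17 without IgG1 replicates 2, 3, 4 and 5. Without 3P10 replicates 1 to 5 it was 17, 12, 15, 12 and 10. With a term for the 4 libraries that stood apart it was 668, which held all 28, and without those 4 it was 18, of which 9 were among the 28. In a fit of the 3P10 and IgG1 libraries alone it was 7.

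Of 20 glucocorticoid response genes 4 fell in 3P10 against IgG1 muscle, 12 when adjusted over the list alone, with a median of -0.83 (adjusted p = 1.45e-17 by camera, adjusted p = 0.00430 with an estimated correlation). Of 24 atrophy genes 1 fell, 7 when adjusted over the list alone (adjusted p = 4.61e-08 by camera, adjusted p = 0.0591 with an estimated correlation). Of 17 acute phase and cytokine response genes 1 fell, 4 when adjusted over the list alone (adjusted p = 0.0127 by camera, adjusted p = 0.290 with an estimated correlation). Of 18 circadian clock genes 1 fell, 3 when adjusted over the list alone (adjusted p = 0.00909 by camera, adjusted p = 0.190 with an estimated correlation), and 22 autophagy and lysosome genes ranked lower with 0 called (adjusted p = 0.0293 by camera, adjusted p = 0.429 with an estimated correlation). Of 19 thermogenic genes 1 rose, 3 when adjusted over the list alone (adjusted p = 6.10e-07 by camera, adjusted p = 0.115 with an estimated correlation). Oxidative phosphorylation (adjusted p = 7.27e-06 by camera, adjusted p = 0.581 with an estimated correlation) and beta-oxidation (adjusted p = 5.11e-05 by camera, adjusted p = 0.429 with an estimated correlation) ranked higher with 0 of 54 and 0 of 23 called. Of 22 collagen and extracellular matrix genes 0 passed, and 2 were higher and 1 lower when adjusted over the list alone (adjusted p = 4.16e-05 by camera, adjusted p = 0.429 with an estimated correlation). Endothelial markers (adjusted p = 2.45e-04 by camera, adjusted p = 0.429 with an estimated correlation), fatty acid synthesis (adjusted p = 0.0127 by camera, adjusted p = 0.581 with an estimated correlation), cholesterol synthesis (adjusted p = 0.0445 by camera, adjusted p = 0.429 with an estimated correlation) and interferon response genes (adjusted p = 0.0155 by camera, adjusted p = 0.429 with an estimated correlation) ranked higher with 0 called.

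Between 3P10 and NTB muscle, edgeR called 0 of 13283 genes, with 563 at an unadjusted p under 0.05, and DESeq2 called 15. With a term for the 4 libraries that stood apart, edgeR called 5. Ddit4 gave 0.12, SE 0.58, adjusted p = 1, Fbxo32 0.52, SE 0.30, adjusted p = 1 and Col6a2 -1.01, SE 0.21, adjusted p = 0.384. Of 22 collagen and extracellular matrix genes 14 were lower in 3P10 when adjusted over the list alone, with a median of -0.69 (adjusted p = 1.39e-29 by camera, adjusted p = 0.0141 with an estimated correlation). Of 17 acute phase and cytokine response genes 2 were higher when adjusted over the list alone (adjusted p = 3.35e-11 by camera, adjusted p = 0.00492 with an estimated correlation). Of 12 fibroblast and preadipocyte markers 3 were lower (adjusted p = 2.79e-07 by camera, adjusted p = 0.0742 with an estimated correlation), of 19 cell cycle genes 2 were lower (adjusted p = 0.00566 by camera, adjusted p = 0.101 with an estimated correlation) and of 4 neutrophil markers 1 was higher (adjusted p = 0.00108 by camera, adjusted p = 0.0726 with an estimated correlation), each when adjusted over the list alone. In the other lists that ranked apart, 0 members passed. Atrophy (adjusted p = 3.35e-05 by camera, adjusted p = 0.0894 with an estimated correlation), autophagy and lysosome (adjusted p = 9.99e-06 by camera, adjusted p = 0.0742 with an estimated correlation), proteasome (adjusted p = 0.00328 by camera, adjusted p = 0.628 with an estimated correlation) and glucocorticoid response genes (adjusted p = 0.00792 by camera, adjusted p = 0.213 with an estimated correlation) ranked higher. So did adipocyte identity (adjusted p = 1.30e-07 by camera, adjusted p = 0.157 with an estimated correlation), lipolysis (adjusted p = 7.24e-04 by camera, adjusted p = 0.343 with an estimated correlation), triglyceride synthesis (adjusted p = 1.97e-04 by camera, adjusted p = 0.157 with an estimated correlation) and fatty acid synthesis (adjusted p = 0.00178 by camera, adjusted p = 0.388 with an estimated correlation). Thermogenic genes (adjusted p = 4.19e-04 by camera, adjusted p = 0.157 with an estimated correlation), fasting-responsive PPAR targets (adjusted p = 6.70e-04 by camera, adjusted p = 0.183 with an estimated correlation), cAMP-responsive genes (adjusted p = 0.00243 by camera, adjusted p = 0.207 with an estimated correlation) and integrated stress response genes (adjusted p = 0.0102 by camera, adjusted p = 0.343 with an estimated correlation) were higher in rank. Slow-fibre genes (adjusted p = 0.00709 by camera, adjusted p = 0.407 with an estimated correlation) and macrophage markers (adjusted p = 0.0430 by camera, adjusted p = 0.534 with an estimated correlation) ranked higher and Schwann and nerve markers (adjusted p = 1.97e-04 by camera, adjusted p = 0.157 with an estimated correlation) lower.

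**Figure D5:**
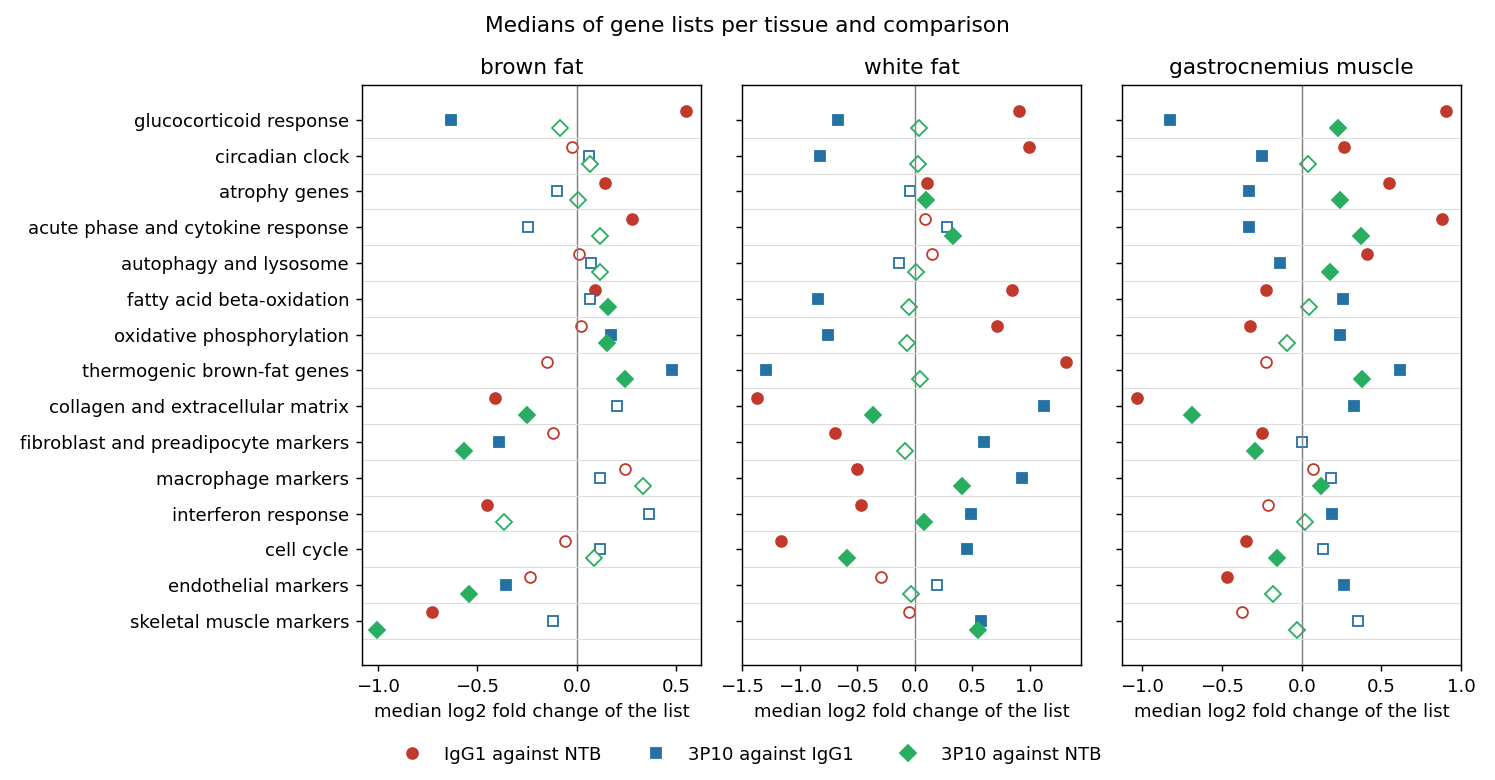
Median log2 fold change of gene lists in the 3 tissues, with circles for IgG1 against NTB, squares for 3P10 against IgG1 and diamonds for 3P10 against NTB, filled where the camera adjusted p was under 0.05. Collagen and extracellular matrix genes lay at -1.37 in white fat and -1.03 in muscle in IgG1 against NTB.

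Genes that passed in IgG1 against NTB were compared with those that passed in 3P10 against IgG1, for overlap and direction. In brown fat 151 genes passed in both comparisons with opposite signs, 105 of them higher in IgG1 against NTB and lower in 3P10 against IgG1. In white fat there were 635, of which 316 were higher in IgG1 against NTB, Mycl, Irf4 and Per1 among them, and 319 lower, such as Ngfr, Fbn1 and Col1a2. In muscle there were 26, of which 16 were higher in IgG1 against NTB, among them Ddit4, Cebpd and Sgk1, and 10 lower, among them Nmrk2 and Dio2. Genes called in both with the same sign numbered 0 in each tissue. Independent lists of these sizes would share 14.9, 46.3 and 0.779 genes of opposite sign, and an unchanged 3P10 group in simulation gave a mean of 0, 0 and 0.05, near 0 by construction since almost no gene can then pass in 3P10 against IgG1. Genes that rose in IgG1 against NTB had medians of 0.61, 0.64 and 0.70 there and 0.08, 0.08 and 0.20 in 3P10 against NTB. Genes that fell had -0.70, -1.01 and -0.93, then -0.16, -0.17 and -0.42. Selection by IgG1 against NTB inflates the first medians, to an untested extent. In brown fat 23 of the 259 calls were also called in 3P10 against NTB.

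Because the IgG1 libraries stand on both sides, folds run against each other by construction. Across genes, which are not independent replicates, the correlation of both folds was -0.612 in brown fat, -0.843 in white fat and -0.785 in muscle, against -0.321, -0.231 and -0.270 in the simulations with an unchanged 3P10 group and -0.561, -0.497 and -0.503 in simulations with no effect at all. The brown fat value lay near the latter. The covariance was -0.0748, -0.320 and -0.120 against -0.0273, -0.0514 and -0.0400 with an unchanged 3P10 group and -0.0266, -0.0507 and -0.0395 with no effect. With separate IgG1 libraries for each comparison, the median correlation over 20 fits was -0.312, -0.592 and -0.414. The median number of opposite calls was then 15, 5 and 5, with 0 to 59, 0 to 137 and 0 to 105. Of the genes then called in IgG1 against NTB, a median of 90.0, 96.1 and 96.1% had the opposite sign in 3P10 against IgG1, at the lowest 63.1, 65.0 and 61.3%, over the 17, 18 and 20 fits with calls. The brown fat count of 151 was 282 without IgG1 replicate 2, 53, 82 and 28 without IgG1 replicates 3, 4 and 5, and 88 without NTB replicate 5 or 6. The white fat count of 635 ran from 96 without IgG1 replicate 2 to 1572 without IgG1 replicate 3, with 11 of its libraries moving it more than 1.5-fold. The muscle count of 26 ran from 8 without IgG1 replicate 4 to 219 without IgG1 replicate 1, with 14 libraries doing so.

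Differences in effect between white fat and muscle were tested in 14898 genes, with libraries taken as independent. Whether both tissues came from the same mice is not stated, and with a replicate block the counts below were 21 and 5. In IgG1 against NTB the effect differed in 166 genes, 96 with the higher fold in white fat and 70 with the lower. Dio2 gave 3.11 (SE 1.11) in white fat and -1.90 in muscle, a difference of 5.04 (SE 1.21, adjusted p = 0.0350 by edgeR). Mfsd2a, Mycl, Ngfr, Doc2b, Eif4ebp1, Gadd45a and Socs3 also differed, with Gadd45a at -0.90 in white fat and 1.08 in muscle, a difference of -1.95 (SE 0.34). In 3P10 against IgG1 31 genes differed, 16 higher and 15 lower in white fat, among them Gadd45a at a difference of 1.56 (SE 0.34, adjusted p = 0.0415). The count of 166 ran from 44 without white fat IgG1 replicate 4 to 582 without white fat IgG1 replicate 3, with 16 libraries moving it more than 1.5-fold. The count of 31 ran from 4, among others without white fat 3P10 replicate 2 and muscle IgG1 replicate 4, to 562 without white fat IgG1 replicate 3, with 19 libraries doing so. Differences that involve brown fat were not tested.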

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

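The tests on the 4 muscle libraries that stood apart, on Krt14 in white fat and on brown fat of 3P10 against NTB were chosen after those results were seen, as were the batch term and the fits limited to the lower library numbers. The Zic1 test, the test of the higher library numbers in white fat and the counts over other splits were chosen earlier.

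Some values of named genes lay far from the rest of their group, by the gap to the nearest library as a share of the group's range, on log2 CPM with 0.5 CPM added. Chance puts about 1 in 20 groups past the critical value, and 39 of 465 groups tested were past it where chance gives 23.25. In brown fat NTB replicate 1 lay low in Gpnmb (0.705) and high in Lipe (0.662) and Dcn (0.78). NTB replicate 4 lay high in Fkbp5 (0.795), at 94.9 CPM against at most 20.9 CPM in others of the group, and low in H2-Eb1 (0.826), and NTB replicate 2 high in Acaca (0.706). IgG1 replicate 2, without which more brown fat genes passed in IgG1 against NTB, lay high in Ucp1 (0.764) and low in Adipoq (0.739) and Klf9 (0.807). IgG1 replicate 4 lay high in Cox6b1 (0.752) and low in Pecam1 (0.936), and IgG1 replicate 1 high in Dcn (0.782). 3P10 replicate 3 had the largest brown fat total, 2.46 M counts (0.631), and 3P10 replicate 5 lay low in Adrb3 (0.77), at 289.7 CPM.

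In white fat IgG1 replicate 4 had the largest total, 80.7 M counts (0.837), and lay high in Hlf (0.792), and IgG1 replicate 5 lay high in Ccl8 (0.715). NTB replicate 5 lay high in Mt1 (0.852) and low in Col1a2 (0.908), NTB replicate 4 low in Acot2 (0.811), NTB replicate 2 high in Ccnb1 (0.886) and NTB replicate 1 high in Cd34 (0.749). 3P10 replicate 3 lay low in Acot2 (0.776), 3P10 replicate 4 low in Akr1cl (0.728), 3P10 replicate 5 low in Fn1 (0.761) and 3P10 replicate 2 low in Ccnb2 (0.821). In muscle NTB replicate 3 lay high in Cebpd (0.838) and Map1lc3b (0.812), NTB replicate 4 high in Kera (0.742) and Serpinh1 (0.85) and NTB replicate 5 low in Dio2 (0.721). IgG1 replicate 2 lay high in Gadd45a (0.875), IgG1 replicate 5 high in Il6ra (0.741) and IgG1 replicate 1 high in Mstn (0.724). 3P10 replicate 2 lay high in Cebpb (0.748) and Cd34 (0.735) and low in Fbxo31 (0.752). 3P10 replicate 1 lay low in Postn (0.756) and 3P10 replicate 5 high in Top2a (0.759).

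Effects that differed between white fat and muscle by the tissue-by-group term came to 9 of 186 differences tested for named genes. In IgG1 against NTB the difference, white fat minus muscle, was 7.73 for Mfsd2a, 5.04 for Dio2 and 2.67 for Mycl, which rose by 3.50 in white fat and gave 0.85 in muscle. It was -3.74 for Ngfr, which fell by 2.97 in white fat and gave 0.82 in muscle. It was -2.29 for Doc2b, -1.76 for Eif4ebp1, -1.95 for Gadd45a and -1.47 for Socs3, a brake on cytokine signalling that rose by 1.42 in muscle and gave -0.07 in white fat. In 3P10 against IgG1 the difference was 1.56 for Gadd45a.

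Muscle NTB replicate 3, IgG1 replicates 2 and 4 and 3P10 replicate 2 stood apart from the other 11 muscle libraries, and their numbers in the sample titles are 14 or higher. A difference in library size does not account for it, since 3 of the 4 totals lay inside the range of the others, and neither does tumour or antibody, since the NTB library of the 4 lay at 30.7 on the first component beside the others. Gene length bias is a candidate explanation that stays open and may reflect library preparation or RNA quality: across genes, the fold within groups fell with transcript length, rho -0.363, outside the range of -0.360 to 0.340 over 249 other choices of 4 libraries. Transcripts of up to 811 bases had a median of 0.21 and those of 2519 bases or more a median of -0.33.

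White fat IgG1 replicates 2 and 4 held Ucp1 at 3250 and 2960 CPM (in this paragraph before TMM scaling), and the white fat count of IgG1 against NTB was 439 or 463 without either, 84 in the fit that left out both along with 2 other libraries, 344 without NTB replicate 1 and 2212 or 2354 without IgG1 replicates 1 or 3. Brown fat pieces would bring the depot gene Zic1, which reached at most 0.226% of the level that their share of Ucp1 would need, while the white depot gene Hoxc10 lay at 18.5 and 17.7 CPM, against 17.6 to 29.1 CPM in other white fat and 0.0541 CPM in brown fat, although Hoxc8, which brown fat held at 66.9 CPM, lay at 55.7 and 41.5 CPM below other white fat (70.5 CPM or more) and Lhx8 in replicate 4 at 0.112 CPM above it (0.0537 CPM or less), 4.29% of its brown fat level. A batch of the higher numbers that acts alike in white fat and muscle is argued against by their within-group folds (correlation -0.0630, 12896 genes). One in white fat alone stays open, above all for replicate 4, apart in total and title index. Krt14, for epithelial carry-over, topped the other 13 libraries only in replicate 4 (267 CPM, 0.796 CPM in replicate 2). This stays open there but not for the pair. Stronger thermogenic gene expression in white fat of some tumour-bearing mice may be a biological source. It was not tested, as no body weights or tumour sizes are given.

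Brown fat held 501 genes that differed between 3P10 and NTB, where edgeR called 0 in white fat and in muscle, and the difference between tissues was not tested. Skeletal muscle pieces brought at least 1/2 of the fold in 0% of those genes, as the estimated muscle shares averaged 0.663% in NTB, 0.382% in IgG1 and 0.335% in 3P10. With the muscle marker score in the fit 313 genes passed, of which 273 were among the 501, and for the 228 calls that ended the median fold went from 0.47 to 0.45 in the same direction while the median SE went from 0.13 to 0.14. A like fall in all cells other than adipocytes would move their markers alike, but the medians of endothelial, fibroblast and macrophage markers lay 0.90 apart. That gap cannot speak to a lower share of endothelial cells and fibroblasts without macrophages. This stays open, since both of those marker lists ranked lower in 3P10 against NTB. The order of library preparation cannot be told apart from the groups, since brown fat libraries were numbered group by group with 0 overlaps between neighbouring groups. It could be a source of this difference and of those in the other brown fat comparisons. An effect of tumour or antibody stays open as well.

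Chance as the source of the counts was tested by regrouping the libraries, with the real split among those drawn. In brown fat 1 of 100 splits, the real one, gave as many genes in IgG1 against NTB (259, highest other 33), in 3P10 against IgG1 (1013, highest other 40), in opposite calls (151, highest other 8) and in 3P10 against NTB (501, highest other 329). In white fat 1 of 100 did so in IgG1 against NTB (1245, highest other 72) and in opposite calls (635, highest other 1). In white fat of 3P10 against IgG1 4 of 100 did so (1068, highest other 1609). The split with 1609 set IgG1 replicates 1 and 3 with 3P10 replicates 2, 3 and 5, which points to sample structure. In muscle 2 of 100 did so in IgG1 against NTB (744, highest other 1671). The split with 1671 set IgG1 replicate 1 with NTB replicates 1, 2, 4 and 5, again sample structure. In muscle 1 of 100 did so in 3P10 against IgG1 (28, highest other 1) and in opposite calls (26, highest other 0). Taken alone, each count but opposite calls excludes chance at 0.05. Regrouping left a median of 0 genes in 3P10 against IgG1, so it cannot test opposition. The 0 of 3P10 against NTB was reached by 100 of 100 splits in white fat (highest other 118) and in muscle (highest other 79). For differences between white fat and muscle, with same-numbered libraries moved together, 2 of 60 splits gave as many in IgG1 against NTB (166, highest other 279). That share is under 0.05, taken alone. In 3P10 against IgG1 3 of 60 did so (31, highest other 53), where chance cannot be excluded.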

How the results depend on the processing

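The term for the 4 muscle libraries that stood apart, and the fits limited to library numbers up to 12, were chosen after seeing the data; the other alternatives were planned. The cause was not tested for any change given here unless stated. Across alternatives 9057 of 10167 values of named genes kept their direction and their side of the threshold, 980 lost the call, 130 gained it and 0 reversed. With RLE factors in edgeR all 575 values kept their call.

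DESeq2 called more genes in white fat and muscle. It gave 2551 in white fat of IgG1 against NTB, 2282 in 3P10 against IgG1, 19 in 3P10 against NTB and 1513 opposite calls. In muscle it gave 1326, 284 and 15, and 261 opposite calls. For differences between white fat and muscle it gave 556 and 388. DESeq2 counts in brown fat, and all counts with RLE factors or with at least 1 CPM in 5 libraries, stayed within 1.5 times. Without a low-count filter the difference between tissues in 3P10 against IgG1 was 8 genes, with 19979 genes tested in place of 14898.

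Fits of the compared groups alone, with fewer libraries behind the spread, gave 154 genes in brown fat of IgG1 against NTB, with 99 opposite calls. They gave 105 in white fat of 3P10 against IgG1, with 84 opposite calls, and 347 and 7 in muscle, with 6 opposite calls. With the replicate block the counts were 164 in brown fat of IgG1 against NTB, with 99 opposite calls, and 418 and 12 in muscle, with 12 opposite calls. The differences between tissues were then 21 and 5. The labels do not state that a number marks 1 mouse. Same-numbered white fat and muscle libraries correlated at a mean of 0.0443 (-0.112 to 0.154), others at -0.00349. Of 15 white fat libraries 7 went best with their own number among all 15 in muscle, more than by chance. With the same numbers per group in both tissues, that favours pairing, though correlations were low and not every pair showed it.

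With the term for the 4 libraries the muscle counts were 2455, 668 and 5, with 616 opposite calls. With library numbers up to 12, which leaves fewer samples, white fat gave 84 genes in IgG1 against NTB and 0 in 3P10 against IgG1 (2321 at an unadjusted p under 0.05), with 0 opposite calls. Muscle gave 18 in 3P10 against IgG1, and the differences between tissues were 20 and 2. With separate IgG1 libraries for each comparison, which leaves 2 or 3 of them, the median of opposite calls was 15 in brown fat, 5 in white fat and 5 in muscle.

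Gene lists gave 946 of 1197 alternative values of the same direction and call, with 216 weaker, 31 stronger and 4 reversed. The 4 reversed with library numbers up to 12, and the values are adjusted p by camera. Thermogenic genes in white fat went to 0.286 in IgG1 against NTB and to 0.424 in 3P10 against IgG1. Mesothelial and epithelial markers in white fat went to 0.0131 and proteasome subunits in muscle to 0.0161, both in 3P10 against IgG1. With an estimated correlation, lists called in IgG1 against NTB, 3P10 against IgG1 and 3P10 against NTB went from 10, 7 and 13 to 0, 0 and 0 in brown fat, from 14, 14 and 11 to 0, 0 and 2 in white fat and from 14, 13 and 20 to 4, 1 and 2 in muscle. With fry they were 1, 4 and 6, then 9, 8 and 2, then 8, 2 and 2. With library numbers up to 12 they were 11, 16 and 12 in white fat, of which 8, 9 and 10 had been called with all libraries, and 13, 12 and 19 in muscle, of which 12, 7 and 18 had. With the term for the 4 libraries they were 14, 13 and 11 (13, 13 and 11 shared) and 11, 13 and 20 (10, 10 and 19 shared).

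Leaving out 1 library at a time also moved the counts. Brown fat gave 34 to 554 in IgG1 against NTB, 646 to 1120 in 3P10 against IgG1, 172 to 675 in 3P10 against NTB and 28 to 282 opposite calls. White fat gave 344 to 2354, 127 to 2304, 0 to 0 and 96 to 1572. Muscle gave 327 to 1307, 8 to 231, 0 to 0 and 8 to 219. Differences between tissues ran from 44 to 582 and from 4 to 562.

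Depth limits brown fat most, where 3 counts are 1.22 to 3.76 CPM and 8711 genes were tested against 14402 in white fat. There Gdf15, Gfral and Ret were too few to test. In simulation 2-fold changes were recovered in 74.6 to 85.1% of brown fat genes tested, but in 52.2 to 56.7% of muscle genes, where libraries were deeper, so depth was not the only limit.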

Other observations

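The overlap between tissues, and the genes it led to in all 3, were chosen after the genes called in each tissue were seen.

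The tissues shared genes that passed. In IgG1 against NTB white fat and muscle shared 58 genes that rose and 118 that fell, where independent lists of the same sizes would share 14.8 and 16.2 of 12896 genes. In opposite directions 1 and 5 genes moved, against 15.1 and 15.8. Brown and white fat shared 34 that rose and 17 that fell, against 8.37 and 3.65, with 1 and 0 in opposite directions. Brown fat and muscle shared 9 and 8, against 4.60 and 1.98, with 1 and 5 opposite, against 3.42 and 2.66. Genes are not independent of each other, so no p is given for these counts.

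Fbxo31, Glul, Gpcpd1 and Prodh rose in all 3 tissues, where independent lists would give 0.237 of 8633 genes. Fbxo31, Glul and Prodh in muscle, Prodh in white fat, and Gpcpd1, Serpinh1 and Snai2 in every tissue were chosen after their values were seen. Prodh, which starts proline breakdown, rose by 1.57 in brown fat, 1.43 in white fat and 1.42 (SE 0.20) in muscle. Fbxo31 rose by 1.12, 1.41 and 0.52, Glul by 0.72 in brown fat and 1.22 in muscle, and Gpcpd1 by 0.68, 0.74 and 0.61. Serpinh1, a chaperone of collagen folding, fell by 1.41 in white fat and also in brown fat and muscle, and the transcription factor gene Snai2 fell by 0.94, 0.91 and 1.39. 1190002N15Rik and Fam101b also fell in all 3, for 4 genes where independent lists would give 0.0746. Of the genes in all 3, every one of Fbxo31, Glul, Gpcpd1, Prodh, Serpinh1 and Snai2 lost its call in at least 1 tissue when some single library was left out. In brown fat the Snai2 call ended in 9 of 11 such fits and those of Glul and Gpcpd1 in 3 each. In white fat Snai2 lost it in 9 of 10, Gpcpd1 in 8, Prodh in 7 and Serpinh1 in 3, and in muscle Fbxo31 in 8, Glul in 6 and Gpcpd1 in 2.

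In 3P10 against IgG1 brown and white fat shared 44 genes that fell against 21.4 for independent lists, but 10 that rose against 15.3, and 8 and 10 moved in opposite directions, fewer than independent lists would share. Brown fat and muscle shared 1 that rose and 2 that fell, with 0 and 2 in opposite directions, and white fat and muscle shared 3 and 2, with 0 and 0, from the 28 calls in muscle. H2-Eb1 alone rose in all 3, by 1.75 in brown fat, 1.29, SE 0.36, adjusted p = 0.0433 in white fat and 1.20 in muscle, and in white fat it was chosen after its values were seen. Its white fat call ended without IgG1 replicates 2, 4 or 5 or 3P10 replicates 1 to 4, and its muscle call without IgG1 replicates 2 to 5 or 3P10 replicates 1, 2, 4 or 5.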
